A study of Mus musculus with 3 samples.

How the data were processed

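RNA of single cells from mouse pancreas was measured in 3 libraries, 1 per group, built per the labels with the 10x Chromium 3-prime kit, version 3. The groups are a sedentary library labelled none, a sedentary library labelled diabetic and an exercise library labelled diabetic-Exercise. The series description names male db/db mice, which lack a working leptin receptor and become obese and diabetic, and treadmill training that began at 6 weeks of age. The genotype of the mice behind the library labelled none is not given in the sources used here. Each library title ends in 3, whose meaning is not stated, so it was not read as a number of animals.

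The authors deposited, for each library, UMI counts (whole numbers) per gene and barcode, with no normalization, made with Cell Ranger. The submitters' processing notes give version 7.1.0 and the matrix headers give version 6.1.2. Every deposited barcode holds at least 500 UMIs. All 55450 feature identifiers and symbols match the GENCODE M21 annotation of GRCm38, from which gene positions are given. The genome build used for alignment is not given in the sources used here.

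The choices below were made before the data were examined, except where stated. Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs from mitochondrial genes. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5. Its automatic threshold marked 0% of barcodes in each library, so the fallback set beforehand was used and the top 5% by score were removed. Kept barcodes of the 3 libraries were clustered together without integration: 10000 UMIs per cell, log scale, 2000 variable genes, 30 principal components, 15 neighbours with shared-neighbour weights, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. The random seed was 1.

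Clusters were named from 24 fixed marker classes. A name required at least 2 of a class's markers among the 10 leading genes, more than from all other classes together, and at least 3 markers of the class seen in 10% or more of the cells. Leading genes were ranked by fold with 10 CPM added to both sides, among genes with at least 20 UMIs in the cluster. Clusters in which 5 or more of the 10 leading genes were mitochondrial stayed unnamed. Clusters with a median above 50% of UMIs from the 31 acinar markers were called acinar-RNA-rich, and their leading genes were also ranked against the other clusters. These naming details, and the split into acinar-RNA-rich and other clusters, were set after the data were seen. Names are written as endothelial-like and so on, because they rest on markers alone. The share outside acinar-like and unnamed acinar-RNA-rich clusters was also added after the data were seen.

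Shares of kept barcodes carry exact (Clopper-Pearson) 95% binomial intervals. Where a share is 0, the limit is 3 counts of the total. Raw UMIs were summed per class and library for classes with at least 50 cells in all 3 libraries (acinar, ductal, endothelial, fibroblast and macrophage) and scaled with edgeR TMM factors to CPM (UMIs of a gene over the scaled library total, the usual sequencing-depth unit). Ratios carry exact conditional Poisson 95% intervals, and log2 values use a prior count of 0.5. All intervals cover counting error only. A gene with 0 UMIs in 1 library is given as at least a fold, against a floor of 3 UMIs in that library. With 1 library per group, no p-value, no standard error and no count of changed genes was computed.

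Of 31 gene lists fixed before the data were examined, a list was measured where at least 5 members had at least 20 UMIs over the 2 libraries compared. Its median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on expression in 10 bins. A list outside the central 95% of random lists is called apart from them. This is a description of the list in 1 pair of libraries and not a test between groups. In diabetic sedentary over none and exercise over diabetic sedentary together, a member had 0 UMIs in 1 library in 20 of the class and list combinations. With such members at their bound, 5 medians moved by over 0.01, with 0 changes of sign. The largest move was 1.00, for the endothelial identity list in acinar-like cells (from -1.51 to -0.51, diabetic exercise over diabetic sedentary). Exercise over none is not in these counts, and of its medians given here extracellular matrix moved by -0.61.

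Genes were named by a rule set before the data were examined. In endothelial-like cells these are, for each comparison, the 10 genes with the largest and the 10 with the smallest log2 ratio. In the library where a gene was higher it needed at least 50 UMIs, at least 50 CPM and at least 0.5 times the CPM of all other kept cells. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and acinar-marker genes and unnamed gene models were left out. In each other class the 3 largest and 3 smallest were taken. Members of the fixed lists may be named as well. Some genes that the rule takes are not reported here.

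The estimates were tested on simulated data, drawn from the endothelial sums with 200 genes altered. Counts were Poisson draws from a pooled profile, as the intervals assume. Genes were independent, without clumping of UMIs in single cells or differences in cell mix. The results therefore check the computation and not how the intervals or lists behave on real counts. For diabetic sedentary over none, altered genes with a true fold of 2 came back with a median fold of 1.91, and those with a fold of 4 with 3.92. Intervals held the true ratio for 96.1% of 7475 genes. Of 1000 lists of 20 unaltered genes 4.2% were called apart, against 100% of 200 lists with 15 raised members. For diabetic exercise over diabetic sedentary these values were 2.00, 3.98, 96.1% of 8021 genes, 4.9% and 100%.

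Alternatives fixed at the same time were a mitochondrial ceiling of 10%, no cell filter, doublets kept, resolutions 0.5 and 2, each library clustered apart, plain CPM, CPM without acinar, mitochondrial and haemoglobin genes, cells thinned to 1000 UMIs, a minimum of 100 UMIs per list member, shares of cells that are not acinar, and only cells with at most 5% acinar RNA. Alternatives added after the data were seen were subtraction of acinar RNA, acinar-like cells joined with all acinar-RNA-rich barcodes, and endothelial-like cells without acinar-RNA-rich sub-clusters or without cells holding Glycam1, Madcam1, Prox1 or Ccl21a. Named genes without the cell with most of their UMIs in each library and shares outside acinar-RNA-rich clusters were also added. Left out of the gene comparisons were unnamed clusters and classes with fewer than 50 cells in a library, among them B-like, T-like and mural-like cells.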

Results

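Gene expression was measured in single cells of mouse pancreas, in 3 libraries with 1 library per group and no replicates. The library labelled none came from sedentary mice, and the other libraries came from diabetic (db/db) mice that were sedentary or exercised. The libraries held 9958 barcodes and 54128454 UMIs (none), 12743 barcodes and 80185752 UMIs (diabetic sedentary), and 18433 barcodes and 45209034 UMIs (diabetic exercise). Median UMIs per barcode were 3952, 4640 and 1887 in that order, and median genes were 413, 457 and 254. Mitochondrial genes held a median of 0.709%, 2.21% and 6.995% of UMIs, and the 31 acinar markers held 73.7%, 74.9% and 68.6%. After filtering and removal of the top 5% by doublet score, 8711, 11019 and 15069 cells were kept. All groups are given in this order below.

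Endothelial-like cells, which line blood vessels, made up 1.40% (interval 1.16 to 1.67) of kept cells in none, 4.97% (4.58 to 5.40) in diabetic sedentary and 2.495% (2.25 to 2.76) in diabetic exercise, from 122, 548 and 376 cells. Their share was 3.55 times higher (2.91 to 4.36) in diabetic sedentary than in none, and 0.502 times as high (0.439 to 0.573) in exercise as in diabetic sedentary. Acinar-like cells, which make digestive enzymes, were 64.3%, 50.3% and 4.94% of kept cells. A further 18.1%, 27.5% and 79.0% were unnamed barcodes rich in acinar RNA, so that the total against which shares are taken differed between libraries. Outside these acinar clusters, 1535, 2447 and 2417 cells remained, and endothelial-like cells were 7.95%, 22.4% and 15.6% of them, with ratios of 2.82 and 0.695. With only acinar-like cells left out, the alternative set beforehand, the ratios were 2.55 and 0.262, so the size of the second ratio depended on the total. Shares also depend on dissociation and on depth per barcode, which differed between libraries.

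Among cells outside acinar clusters, ductal-like cells were 13.2%, 32.8% and 53.3%, and fibroblast-like cells 19.2%, 21.9% and 13.5%. Macrophage-like cells were 22.4%, 10.1% and 9.14%, and mural-like cells, which wrap small vessels, 2.87%, 5.80% and 3.56%. B-like cells were 14.9%, 0.286% and 0.414% (229, 7 and 10 cells, in a cluster with a median of 51.4% of UMIs from acinar markers), and T-like cells 12.1%, 0.777% and 0.993% (185, 19 and 24 cells). Acinar-like cells lay in different clusters by library: cluster 1 held 3401, 539 and 18 cells, cluster 3 held 721, 2602 and 269, and cluster 8 held 52, 1322 and 299. Ductal-like cluster 14 held 2, 193 and 333 cells, while ductal-like cluster 7 held 201, 610 and 955.

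**Figure D1:**
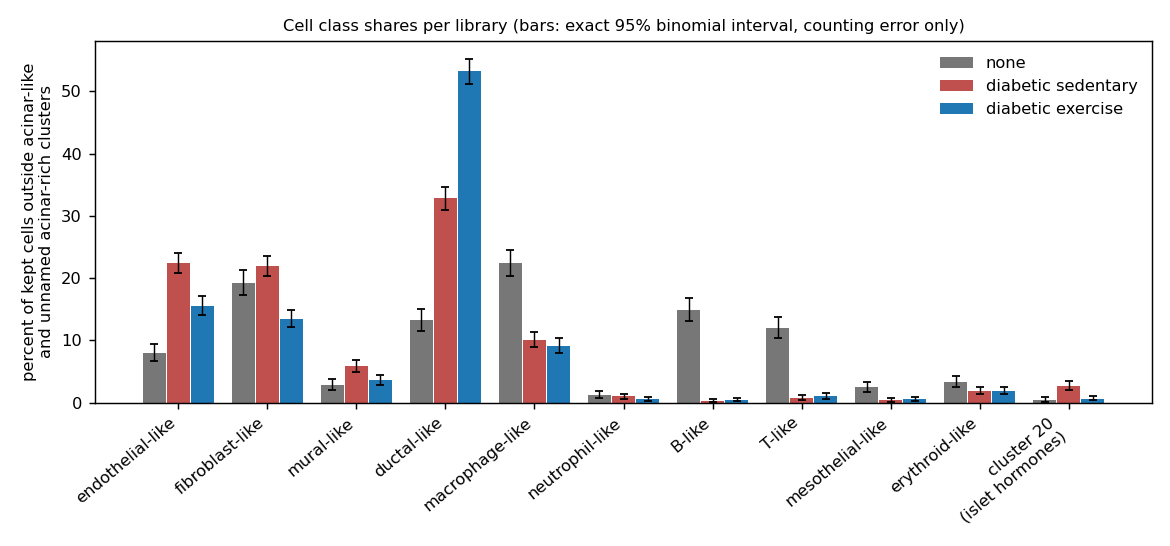
Share of each class among kept cells outside acinar-like and unnamed acinar-RNA-rich clusters, in percent, for the 3 libraries, with exact 95% binomial intervals. Endothelial-like cells stood at 7.95%, 22.4% and 15.6%, and B-like cells at 14.9% in none and under 1% in both diabetic libraries.

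The comparison of diabetic sedentary with none asks how endothelial-like cells of diabetic mice differ from those of the sedentary library labelled none. Genotype and age of the mice of none are not given in the sources used here. Genetic background, age and handling of the library thus cannot be told apart from diabetes in any ratio over none. Genes of capillary lipid handling were higher as a list in the diabetic library, and heat shock genes were lower. Heat shock genes were lower in macrophage-like cells as well, and whether handling of the libraries lay behind this was not tested. Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888801), a fatty acid transporter, stood at 142 CPM in none and 853 in diabetic sedentary, a ratio of 6.03 (4.55 to 8.15). The metallothioneins Mt1 and Mt2 had ratios of 0.125 (0.113 to 0.138) and 0.0856 (0.0624 to 0.117). Other kept cells held Mt1 at 3227, 1039 and 1281 CPM and Mt2 at 588, 133 and 159, and with acinar RNA subtracted 0 UMIs of Mt2 remained in none and in diabetic sedentary. The class summed to 426800, 1743395 and 847794 UMIs, of which acinar markers held 48.1%, 34.0% and 35.6%. All RNA from acinar cells was estimated at 63.6%, 44.0% and 50.2% of the class.

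Of the endothelial markers, Pecam1 stood at 659, 953 and 1163 CPM, Cdh5 (VE-cadherin) at 328, 579 and 507, and Plvap, a component of capillary fenestrae, at 1661, 2253 and 1246. The VEGF receptors Kdr (1548 and 1585 CPM) and Flt1 (2102 and 2254 CPM) lay close together in none and diabetic sedentary. Vwf (ENSMUSG00000001930, chromosome 6, 125546774 to 125686679), the von Willebrand factor of clotting, was 13.4 times higher (3.65 to 112) on 2 UMIs in none. Mgp (ENSMUSG00000030218, chromosome 6, 136872435 to 136875823), a matrix protein that limits calcification, was 19.0 times higher (6.43 to 92.5) on 3 UMIs in none. Edn1, the vasoconstrictor endothelin, was 6.72 times higher (2.57 to 24.98), the lymphatic marker Mmrn1 7.39 times (2.47 to 36.3, on 12 cells of diabetic sedentary, with 0 UMIs in both libraries without cells that held lymphatic or venule genes) and the transporter Abcc4 9.30 times (2.51 to 77.8). Cd274, the immune checkpoint ligand PD-L1, was 7.14 times higher (2.38 to 35.1), and Gbp4, an interferon-induced GTPase, 7.68 times (4.002 to 16.9). H2-Aa, of MHC class II, was 23.7 times higher (4.17 to 942) on 1 UMI in none, and lower with doublets kept (log2 -0.89). Reg2, an acinar secreted protein, was 8.18 times higher (6.98 to 9.65), and other kept cells held more of it (581, 7334 and 2461 CPM).

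Among genes lower in diabetic sedentary, the heat shock genes Hspa1b and Hspa1a had ratios of 0.136 (0.0971 to 0.189) and 0.247 (0.188 to 0.325). Tff2 and Pla2g1b, secreted by the exocrine pancreas, had ratios of 0.213 and 0.218, and Hamp2 0.219. Other kept cells held Tff2 at 3176, 1186 and 1311 CPM, Pla2g1b at 3972, 1615 and 1578 and Hamp2 at 141, 78.0 and 87.0. With acinar RNA subtracted, 0 UMIs of Tff2 remained in none and in diabetic sedentary. Glycam1 (ENSMUSG00000022491, chromosome 15, 103562759 to 103565081), made by the venules through which lymphocytes enter lymph nodes, had 869 UMIs in none and 0 in both diabetic libraries. It was at least 1542-fold lower in diabetic sedentary, and 836 of its UMIs came from 1 cell of none. Madcam1, of the same kind of venule, had a ratio of 0.0209 that rested on 152 UMIs in 1 cell, without which its log2 ratio was 0.65. Igfbp5 had a ratio of 0.0450, with 43 of its 71 UMIs in none from 1 of 2 cells, and with libraries clustered apart it was higher (log2 1.33).

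**Figure D2:**
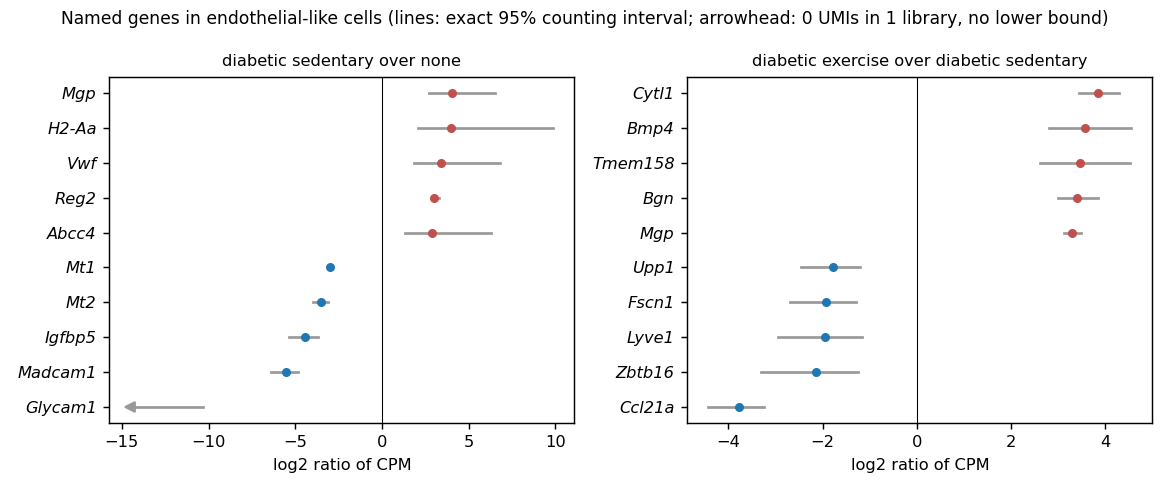
Log2 ratio of CPM for the 5 named genes with the largest and the 5 with the smallest ratio of each comparison in endothelial-like cells, with exact 95% counting intervals. Mgp lay to the right of 0 in both panels, at ratios of 19.0 and 9.85, and the arrowhead marks Glycam1, with 0 UMIs in diabetic sedentary.

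Gene lists of endothelial-like cells that stood apart from random lists, diabetic sedentary over none, are given with their median log2 ratio and percentile. Of capillary lipid handling, 9 of 12 members were higher (median 0.54, percentile 99.7), among them Cd36 and Fabp4 (ratio 1.76, 1.67 to 1.85). With the member at 0 UMIs in none at its bound this median was 0.50. For MHC class I, 11 of 12 were higher (0.45, percentile 99.4), among them Tap2 (2.47, 1.41 to 4.74) and H2-D1 (1.37, 1.24 to 1.53). All 5 members of MHC class II were higher (2.03, percentile 99.99), with Cd74 at 4.04 (2.27 to 7.92) and H2-Ab1 at 4.19 (1.98 to 10.6). Extracellular matrix had 5 of 7 higher (1.09, percentile 99.97), and mitochondrially encoded genes 12 of 12 (1.40, percentile 100). Heat shock genes were lower in 13 of 14 (-0.88, percentile 0), with Dnajb1 at 0.358 (0.254 to 0.509) and Hsp90aa1 at 0.488 (0.379 to 0.635). Lower as well were immediate early genes, the fast transcriptional response to stimuli (14 of 19, -0.30, percentile 0.73), and the unfolded protein response (16 of 20, -0.27, percentile 1.29). Nuclear genes of oxidative phosphorylation were lower in 19 of 27 (-0.27, percentile 0.39), acinar digestive enzymes in 21 of 23 (-1.19, percentile 0) and macrophage residence and repair genes in 4 of 6 (-0.54, percentile 0.90). With doublets kept, MHC class II turned lower (-0.86) and MHC class I came within random lists (0.33). With cells thinned to 1000 UMIs, where the median of all genes moved to 0.32, the immediate early, unfolded protein and oxidative phosphorylation lists came within random lists (-0.026, 0.0074 and 0.040, percentiles 2.81, 6.71 and 7.26), and macrophage residence turned higher (0.41, and 0.31 with libraries clustered apart). With acinar RNA subtracted, the unfolded protein, oxidative phosphorylation and MHC class I lists came within random lists (0.10, 0.020 and 0.36).

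Lists within the central 95% of random lists were led by nitric oxide and flow response (13 of 19 higher, median 0.26, percentile 96.8) and endothelial junction and barrier (12 of 16 higher, 0.25, percentile 97.4). Interferon response had 11 of 20 members higher (0.24, percentile 94.6), with Gbp2 at 5.31 (2.53 to 13.4) and Isg15 at 150 and 73.3 CPM. Medians of endothelial identity, VEGF and angiopoietin signalling, adhesion and inflammation, and basement membrane were 0.16, 0.11, 0.05 and 0.07. Endothelial to mesenchymal transition stood at -0.09, oxidative stress defence at 0.11, hypoxia response at 0.10, glycolysis at -0.11 and apoptosis at -0.01. Autophagy, insulin signalling, the cell cycle, acinar injury and beta cell dedifferentiation stood at 0.01, 0.13, -0.43, -0.11 and 0.21.

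**Figure D3:**
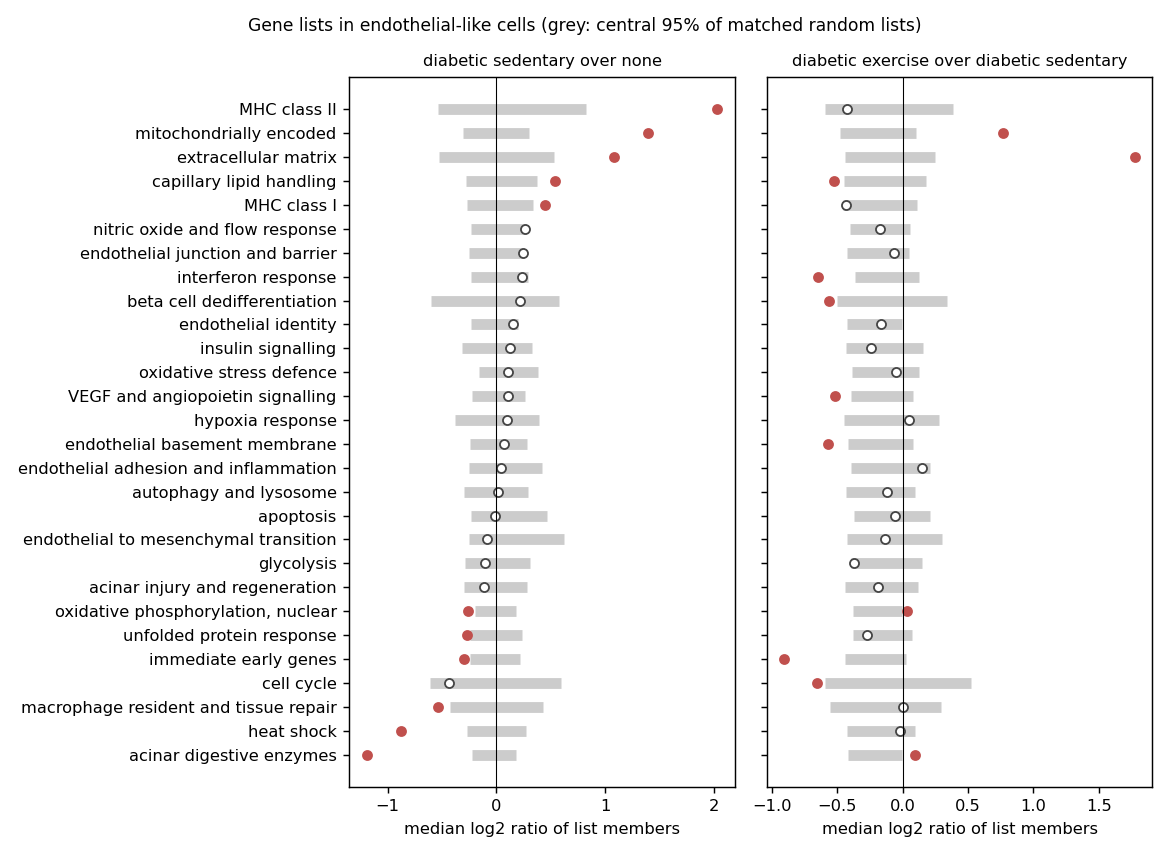
Median log2 ratio of each gene list in endothelial-like cells for both comparisons, over grey bars that hold the central 95% of matched random lists; filled points lie outside the bars. Capillary lipid handling lay above the bar for diabetic sedentary over none (0.54) and below it for exercise over diabetic sedentary (-0.52).

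The comparison of diabetic exercise with diabetic sedentary is the one the series is about, the effect of training on endothelial cells of the diabetic pancreas. Endothelial-like cells of the exercise library held more RNA of extracellular matrix genes and less of immediate early, interferon, basement membrane, VEGF and capillary lipid genes. The mix of endothelial sub-clusters also differed: sub-cluster 2 held 180 cells in diabetic sedentary and 37 in exercise, and sub-cluster 4 held 15 and 38. Sub-cluster 1, with a median of 57.3% of UMIs from acinar markers, held 89 of 548 cells in diabetic sedentary and 168 of 376 in exercise. Only the genes that the naming rule took as higher in exercise were weighted by sub-cluster. Whether the mix lay behind the list medians or the lower genes was not tested. Both comparisons share the diabetic sedentary library, whose chance values enter them with opposite sign, so exercise over none is given for the lists that stood apart, after the others. Bgn (ENSMUSG00000031375, chromosome X, 73483602 to 73495933), the matrix proteoglycan biglycan, stood at 30.3 CPM in diabetic sedentary and 321 in exercise, a ratio of 10.6 (7.95 to 14.3). In the 5 endothelial sub-clusters with enough cells of both libraries, log2 of Bgn was 2.36, and it fell to 0.85 with these weighted as in diabetic sedentary. Rgcc (ENSMUSG00000022018, chromosome 14, 79288756 to 79301645), a cell cycle regulator, stood at 1205, 1199 and 351 CPM, a ratio of 0.293 (0.2602 to 0.329).

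Of genes higher in exercise, the secreted protein Cytl1 (ENSMUSG00000062329, chromosome 5, 37735519 to 37739820) had a ratio of 14.5 (10.9 to 19.6) and 0 UMIs in none. The growth factor Bmp4 had a ratio of 12.3 (6.97 to 23.5), Tmem158 11.4 (6.13 to 23.1) and Mgp 9.85 (8.70 to 11.2). Fn1, fibronectin, was 9.39 times higher (5.33 to 17.7), and Vwf 6.57 times (5.44 to 7.98). Weighted as Bgn was, log2 fell from 2.14 to 0.56 for Cytl1, 2.297 to 0.81 for Bmp4, 1.90 to 0.82 for Mgp, 2.03 to 1.27 for Fn1, 2.52 to 1.24 for Tmem158 and 2.405 to 0.63 for Vwf. Igfbp5 was 8.52 times higher (4.97 to 15.4) on 10 cells of exercise, with 35.6% of its UMIs in 1 cell. Hspa1b was 7.45 times higher (5.64 to 9.95) and stood at 255, 34.6 and 257 CPM. With the same weights Igfbp5 went from 2.897 to 2.175 and Hspa1b rose from 2.67 to 3.14. Edn1 was 3.15 times higher (2.54 to 3.91), Nos3, the endothelial nitric oxide synthase, 1.58 times (1.12 to 2.23) and Cldn5, a tight junction protein, 2.71 times (2.09 to 3.52).

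Of genes lower in exercise, the VEGF receptors Kdr and Flt1 had ratios of 0.565 (0.523 to 0.610) and 0.514 (0.481 to 0.550). The lymphatic genes Ccl21a (0.0719, 0.0467 to 0.106) and Lyve1 (0.2503) rested on 15 and 11 cells of diabetic sedentary. Without cells that held lymphatic or venule genes, both libraries had 0 UMIs of Ccl21a, and Lyve1 had 0 in diabetic sedentary and 3 in exercise, so that no ratio could be given. Zbtb16, a transcription factor, had a ratio of 0.218 (0.101 to 0.419), Fscn1, an actin bundler, 0.259 (0.156 to 0.409) and Upp1, uridine phosphorylase, 0.287 (0.182 to 0.434). Rtl8a (0.314, 0.224 to 0.432), the pericyte marker Rgs5 (0.324, 0.219 to 0.468), Sertad1 (0.337, 0.226 to 0.490) and the pseudogene Tpt1-ps3 (0.299) completed the named genes. Angpt2, a vessel remodelling factor, had a ratio of 0.159 (0.0416 to 0.432).

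Immediate early genes were lower in 18 of 19 in exercise (median -0.90, percentile 0), with Fos at 0.515 (0.479 to 0.553), Egr1 at 0.531 (0.485 to 0.579) and Nr4a1 at 0.390 (0.322 to 0.470). Fosb was the member that was higher (1.40, 1.18 to 1.66). The immediate early list was low against random lists in fibroblast-like cells too, and in acinar-like cells except at resolutions 0.5 and 2. The shift was thus not particular to endothelial-like cells, and whether handling of the libraries lay behind it was not tested. Interferon response genes were lower in 19 of 20 (-0.65, percentile 0), with Ifitm3 at 0.592 (0.546 to 0.641) and Bst2 at 0.515 (0.418 to 0.630). For the endothelial basement membrane, 14 of 16 were lower (-0.57, percentile 0.08), with the collagens Col4a1 at 0.484 (0.429 to 0.544) and Col4a2 at 0.376 (0.321 to 0.439). VEGF and angiopoietin signalling was lower in 14 of 19 (-0.51, percentile 0.20) and capillary lipid handling in 9 of 13 (-0.52, percentile 0.72), with Gpihbp1, the anchor of lipoprotein lipase, at 0.492 (0.450 to 0.539). In the same list Cd36 stood at 0.657 (0.594 to 0.725) and Fabp4 at 0.599 (0.581 to 0.618). Extracellular matrix genes were higher in 10 of 13 (1.78, percentile 100), with Eln, elastin, at 4.56 (3.66 to 5.72) and Timp2 at 3.15 (2.33 to 4.28). Mitochondrially encoded genes were higher in 11 of 13 (0.77, percentile 100), beside a median mitochondrial share of 1.24%, 4.47% and 7.75% in these cells. Acinar digestive enzymes (15 of 23 higher, 0.09, percentile 99.8) and nuclear oxidative phosphorylation (14 of 27 higher, 0.03, percentile 98.95) lay above random lists. The cell cycle (5 of 5 lower, -0.65, percentile 1.39) and beta cell dedifferentiation (5 of 6 lower, -0.56, percentile 1.18) lay below them. VEGF and angiopoietin signalling came within random lists with cells thinned to 1000 UMIs (-0.28), and so did capillary lipid handling without a cell filter, where its percentile was 2.94. With acinar RNA subtracted, acinar digestive enzymes stood at -1.25, but the amount subtracted was set from acinar markers, so this value does not give their direction. Acinar digestive enzymes came within random lists with doublets kept (-0.17) and at a mitochondrial ceiling of 10% (-0.012). Nuclear oxidative phosphorylation and beta cell dedifferentiation came within random lists with acinar RNA subtracted (-0.017 and -0.50), with doublets kept (-0.0037 and -0.44) and at that ceiling (-0.016 and -0.47). The former did so also without a cell filter (-0.024) and without acinar-RNA-rich sub-clusters (-0.038). The latter and the cell cycle did so without cells that held lymphatic or venule genes (-0.48 and -0.47).

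Within random lists were endothelial identity (15 of 20 lower, -0.17, percentile 64.4), junction and barrier (-0.07), nitric oxide and flow response (-0.17), adhesion and inflammation (10 of 15 higher, 0.15) and heat shock (-0.02). MHC class I had all 12 members lower (-0.43, percentile 3.71) and MHC class II 4 of 5 (-0.43, percentile 9.59). Unfolded protein response, glycolysis and oxidative stress defence stood at -0.27, -0.37 and -0.05. Endothelial to mesenchymal transition, apoptosis, autophagy, hypoxia response and insulin signalling stood at -0.13, -0.06, -0.12, 0.05 and -0.24. Acinar injury and macrophage residence and repair stood at -0.19 and 0.01. In exercise over none, medians were -1.15 for immediate early genes, -0.60 for interferon response, -0.73 for heat shock, -0.27 for capillary lipid handling, 2.88 for extracellular matrix (2.27 with members at their bound) and -0.11 for MHC class I. They were -0.08 for VEGF and angiopoietin signalling, -0.54 for basement membrane, 2.35 for mitochondrially encoded genes, -1.07 for acinar digestive enzymes, -0.41 for nuclear oxidative phosphorylation and 0.02 for beta cell dedifferentiation. For the unfolded protein response and macrophage residence they were -0.50 and -0.21. For the cell cycle and MHC class II too few members were measured in exercise and none.

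In acinar-like cells, genes of the Reg family, secreted proteins raised in pancreatic injury, were higher in diabetic sedentary than in none and lower in exercise than in diabetic sedentary. Reg2 (ENSMUSG00000023140, chromosome 6, 78395623 to 78408106) stood at 632, 9376 and 2384 CPM, Reg3a at 13.1, 306 and 52.4, Reg3g at 14.0, 246 and 45.2 and Reg3b at 257, 2234 and 554. Reg3a was 23.3 times higher (21.4 to 25.5) in diabetic sedentary than in none, Reg3g 17.6 times (16.1 to 19.2) and Reg2 14.8 times (14.7 to 15.03). Exercise over diabetic sedentary had ratios of 0.171 (0.151 to 0.193) for Reg3a, 0.184 for Reg3g and 0.248 (0.239 to 0.258) for Reg3b. Acinar injury and regeneration genes were higher in 10 of 15 for diabetic sedentary over none (0.41, percentile 99.9) and lower in 11 of 15 for exercise over diabetic sedentary (-0.61, percentile 0). Mt2, Mt1 and Tff2 were lower in diabetic sedentary than in none (0.180, 0.324 and 0.432). In exercise the linker histone Hist1h1c was 2.37 times higher (2.06 to 2.72), the Golgi enzyme Man2a1 1.57 times and the trypsinogen Prss3 2.03 times (1.98 to 2.07). For Prss3, 31.5% of UMIs came from 1 cell, without which log2 was 0.57. Immediate early genes were lower in both comparisons (-0.49 and -0.92, both at percentile 0), and the unfolded protein response was lower in exercise (-0.37, percentile 0.23). Acinar markers held 76.5%, 78.4% and 75.8% of UMIs of the class, which came from different clusters in each library and from 745 cells in exercise. With all acinar-RNA-rich barcodes joined, log2 was 3.92 for Reg2 and 4.52 for Reg3a (diabetic sedentary over none), -2.42 for Reg3a (exercise over diabetic sedentary) and -0.25 for Prss3. The injury list of exercise over diabetic sedentary came within random lists under several other cell selections, among them all acinar-RNA-rich barcodes (-0.24), and above them at resolution 2 (-0.15, percentile 98.8), where the immediate early list came within them (-0.29).

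**Figure D4:**
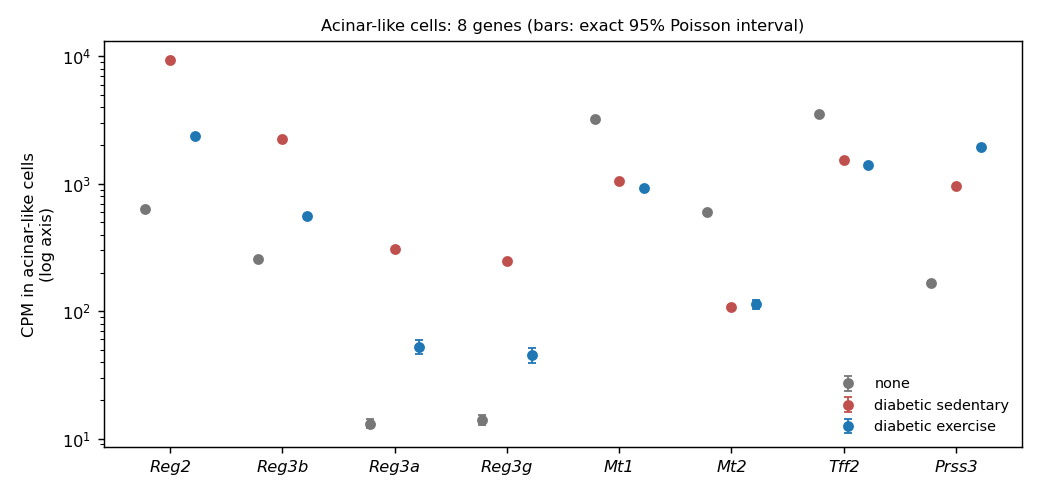
CPM of 8 genes in acinar-like cells of the 3 libraries on a log axis, with exact 95% Poisson intervals. Reg2, Reg3a, Reg3b and Reg3g were highest in diabetic sedentary, and Mt1, Mt2 and Tff2 were highest in none.

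In ductal-like cells, whose acinar marker share was 33.7%, 22.8% and 20.1%, the transcription factor Onecut2 stood at 4.88, 169 and 373 CPM and the membrane protein Tspan8 at 5.69, 194 and 285. These differences accompanied cluster 14, nearly absent from none, and with cells thinned to 1000 UMIs log2 of Onecut2 was 3.26. Hs6st2 (0.167), the neuropeptide Gal (0.251) and Rhov (0.2596) were lower. Other kept cells held more Gal (111, 47.2 and 48.4 CPM) than ductal-like cells (69.1, 17.3 and 10.6). In exercise over diabetic sedentary, cell cycle genes were higher in 14 of 16 (1.44, percentile 100), on few UMIs, with Top2a at 1.37 and 8.63 CPM (6.30, 2.99 to 15.3) and Mki67 at 2 and 33 UMIs (14.8, 3.795 to 128). With at least 100 UMIs per member this list came within random lists (0.090). Hspa1b (3.58, 3.17 to 4.05) and Hspa1a (2.95, 2.61 to 3.35) were higher, and Ier3 (0.303, 0.288 to 0.319), the stress cytokine Gdf15 (0.320, 0.279 to 0.367) and Ppp1r10 (0.323) were lower. Prss3 was 3.63 times higher, with 26.1% of its UMIs in 1 cell. Oxidative stress defence was higher in 17 of 20 for diabetic sedentary over none (0.32, percentile 99.9) and stood at -0.28 (percentile 2.41) for exercise over diabetic sedentary, a value within random lists under several alternatives, such as a mitochondrial ceiling of 10% (-0.23).

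In fibroblast-like cells (acinar marker share 43.2%, 33.3% and 28.6%), the imprinted gene Mest stood at 52.1, 475 and 140 CPM, 9.12 times higher (6.86 to 12.4) in diabetic sedentary than in none. Zim1 was 57.3 times higher (10.1 to 2282) on 1 UMI in none, and of 419 UMIs of the acute phase gene Saa3 332 came from 1 cell. Col1a1, the main fibrillar collagen, stood at 1123, 2174 and 2276 CPM. Adhesion and inflammation genes were lower in diabetic sedentary in 10 of 14 (-0.999, percentile 0), with the chemokines Ccl2 at 322, 64.4 and 43.5 CPM and Cxcl1 at 586, 269 and 73.3. Ccl21a had 185 UMIs in 4 cells of none and 0 in both diabetic libraries, at least 138-fold lower in diabetic sedentary. Car3 had 213 UMIs in 1 cell of none and 0 elsewhere, and 161 of 194 UMIs of Cxcl13 in none came from 1 cell. In exercise over diabetic sedentary, Chodl (19.8, 10.4 to 42.5), Col8a1, a short-chain collagen (13.5, 9.42 to 19.9), and Thbs4, a thrombospondin (10.1, 6.62 to 15.9), were higher. Adamts4, a matrix protease (0.0315, 0.00644 to 0.0938), and Hp, haptoglobin (0.105), were lower. Immediate early genes (18 of 19, -1.18), the unfolded protein response (17 of 19, -0.82) and interferon response (13 of 16, -0.60) were lower in exercise, at percentiles 0, 0 and 0.04. With cells thinned to 1000 UMIs, adhesion and inflammation (-0.13), the unfolded protein response (-0.36) and interferon response (-0.68) came within random lists.

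In macrophage-like cells (acinar marker share 40.01%, 30.1% and 26.7%), interferon response genes were lower in diabetic sedentary than in none in 13 of 14 (-1.13, percentile 0). Among them Irf7, a master regulator of interferon genes, had a ratio of 0.185 (0.0802 to 0.379), and Bst2 of 0.339. The interferon-induced Ifi27l2a had a ratio of 0.108 (0.0878 to 0.132), the chemokine Ccl24 0.110 and Fcna 0.138. Residence and repair genes were lower in 12 of 19 (-0.43, percentile 0.14), with Lyve1 at 461, 141 and 133 CPM and Folr2 at 433, 111 and 129. Of monocyte markers, Plac8 (2.40, 1.93 to 2.99) and Ccr2 (2.40, 1.97 to 2.95) were higher, Ly6c2 stood at 1.12 (0.579 to 2.18) and F13a1 was lower (0.738, 0.675 to 0.807). The mix of monocytes and macrophages in the class was not tested. From the residence and repair list, Arg1 (arginase) and Chil3, also a monocyte marker, had 0 UMIs in none and were at least 26.7-fold and 25.3-fold higher in diabetic sedentary, on 8 and 11 cells. Hp was 6.42 times higher. Cell cycle genes were higher in 10 of 10 in diabetic sedentary (1.504) and lower in 11 of 12 in exercise (-1.54), with Top2a at 7.76, 47.0 and 9.02 CPM. Heat shock genes were lower in 14 of 14 in diabetic sedentary (-0.79) and higher in 12 of 14 in exercise (0.50), where Hspa1b was 4.80 times higher (4.03 to 5.74). In exercise over diabetic sedentary, Mmp12, macrophage elastase, was 11.9 times higher (7.97 to 18.4) on 16 cells, with 31.7% of UMIs in 1 cell, and AA467197 was 15.6 times higher. Plac8 (0.115), Cxcl1 (0.149) and Stmn1 (0.171) were lower.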

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

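The tests of blood, of the mix of endothelial sub-clusters, of RNA from other cells and of depth were chosen after the results were seen, while the bounds for lymphoid tissue, free RNA and loss of cytoplasm were written before.

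B-like and T-like cells were far more frequent in none than in the diabetic libraries. Blood is argued against: outside acinar clusters, erythroid-like cells were 1.77 times (1.16 to 2.69) and neutrophil-like cells 1.20 times (0.611 to 2.30) as frequent in none as in diabetic sedentary, against 52.2 times (24.9 to 131) for B-like and 15.5 times (9.66 to 26.4) for T-like cells. The bound written for lymphoid tissue in the dissected piece was missed. For it, 12 genes of lymphoid stroma were predicted at over 2 times higher in none. Their summed UMIs (946, 2823 and 1607) gave 0.466 (0.430 to 0.506) for the lower of the ratios, but Cxcl12 and Gcnt1 held 733, 2563 and 1365 of these UMIs. Without Cxcl12 and Gcnt1, abundant in all libraries, the bound was missed too, at 1.21 (1.01 to 1.46) over diabetic sedentary and 0.697 (0.577 to 0.842) over exercise, a test chosen after the values were seen. Cr2 (43, 0 and 3 UMIs), Tnfsf11 (23, 5 and 1) and Glycam1, almost wholly from 1 cell, went the other way, lymphoid tissue that brought few stromal cells was not tested, and neither was a difference that goes with diabetes.

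Endothelial-like cells of exercise held more RNA of 10 named genes, among them Mgp, Vwf, Cytl1, Bgn, Fn1, Bmp4, Tmem158, Igfbp5 and Hspa1b, than those of diabetic sedentary. Free RNA from the pool of other kept cells is argued against for the set: the median ratio of CPM in other kept cells to CPM in the class, both without TMM scaling, was 0.053 (0.0034 to 0.913 over the 10 genes), although the rule for naming genes itself capped this ratio, and Igfbp5 is not covered (1.02 with the scaled CPM of the class). Acinar-like and unnamed acinar-RNA-rich barcodes were 4.94% and 79.0% of kept barcodes in exercise. They lead this pool, so the ratio does not speak to droplets shared with a cell of a rarer class. With the 5 of 8 sub-clusters that held enough cells of both libraries, found without these genes and weighted as in diabetic sedentary, the median log2 ratio was 0.84 against 2.33 unweighted, a proportion of 0.360 (0.129 to 0.630 over 1000 redraws of cells). Left out were 41 cells of diabetic sedentary and 21 of exercise, 13 of them in a sub-cluster seen in exercise alone, and over the full class the median was 3.25. The interval of the proportion (0.129 to 0.630) lay wholly below the bound set for a mix without a part. Within sub-clusters 0, 1, 2 and 3, the summed CPM of the 10 genes was 47.8, 65.7, 166 and 330 in diabetic sedentary. In exercise it was 703, 772, 557 and 2787 there. In sub-cluster 4, of 15 and 38 cells, it was 9066 and 9652. The sub-clusters were found from other genes of the same cells, so a change within cells that reached those genes could itself shift the mix. The interval of the proportion also spans the bound of 0.5. How much the mix and higher expression within cells each account for thus cannot be told. An effect of training was not tested.

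Most kept barcodes of exercise were rich in acinar RNA, with few genes and much mitochondrial RNA: unnamed acinar-RNA-rich barcodes, used in no gene comparison, made up 27.5% of kept barcodes in diabetic sedentary and 79.0% in exercise. Genes and mitochondrial RNA were first tested against depth together and were separated after the values were seen. Depth could account for the few genes, since diabetic sedentary barcodes thinned to 1966 UMIs had a median of 205 genes against 237 in exercise barcodes near that depth. The mitochondrial share of these barcodes was 1.58% against 8.31%. Random thinning leaves this share of a barcode unchanged on average, so that outcome was fixed in advance and is no test of depth as its cause. Free RNA without a cell was predicted to hold less of the nuclear RNAs Malat1 and Neat1 than acinar-like cells. In exercise, these RNAs were 1.68 times (1.56 to 1.82) as high in barcodes led by mitochondrial genes as in acinar-like cells, so the bound was missed. Only acinar-like cells were compared and free RNA from other classes was not measured, so free RNA is not excluded. The same value of 1.68 met the bound written for acinar cells that had lost cytoplasm (1.17, 1.09 to 1.247, in diabetic sedentary). It is a share of UMIs and not an amount per barcode, and whether handling or training lay behind it was not tested.

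Several gene lists had medians of opposite direction in different classes under the same comparison, and none of these differences was tested. For diabetic sedentary over none, nitric oxide and flow response was 1.06 log2 units higher in ductal-like than in macrophage-like cells. MHC class I was 0.89 higher in endothelial-like than in macrophage-like cells. MHC class II was 2.69 higher in endothelial-like than in ductal-like cells, but with doublets kept the endothelial-like median was itself negative (-0.86). Macrophage residence and repair genes were 1.36 higher in fibroblast-like than in endothelial-like cells, whose median turned to 0.41 with cells thinned to 1000 UMIs and to 0.31 with libraries clustered apart. For exercise over diabetic sedentary, VEGF and angiopoietin signalling was 0.89 higher in fibroblast-like than in endothelial-like cells, but with thinned cells both were negative (-0.29 and -0.28). Endothelial basement membrane genes were 0.77 higher in ductal-like than in endothelial-like cells, and the ductal-like median was -0.041 with thinned cells. Heat shock genes were 0.83 higher in macrophage-like than in fibroblast-like cells. Cell cycle genes were 2.98 higher in ductal-like than in macrophage-like cells. Cluster 20, which no comparison used and whose leading genes were islet hormones of several cell types, held 0.599% (0.4635 to 0.761) of kept barcodes in diabetic sedentary. In none it held 0.0689% (0.0253 to 0.150), from 6 cells.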

How the results depend on the processing

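The subtraction of acinar RNA, the joined acinar-RNA-rich barcodes, shares outside them, the endothelial subsets and genes without their top cell were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out and no other split of samples was tried. Of 22 endothelial list results apart from random lists, 10 stayed so under every alternative run, and 247 of 277 alternative values kept direction and side. Of 88 named gene results, 40 were the same throughout. Of their 1027 alternative values, 6 changed sign and 133 moved outside the counting interval. No value is given where both libraries had at most 3 UMIs of the gene, a limit applied to the alternatives only after their values were seen. It left out 9 values, of which 3 had changed sign. The share ratio of endothelial-like cells ran from 2.55 to 4.197 for diabetic sedentary over none and from 0.262 to 0.695 for exercise over diabetic sedentary. Not run were cells with at most 5% acinar RNA, since the library labelled none held 0 such endothelial-like cells, and macrophage-like cells with libraries clustered apart, a class then not found in each library. Plain CPM moved the median of all genes, diabetic sedentary over none, to 0.43 in endothelial-like, -0.19 in acinar-like, 0.28 in ductal-like, 0.35 in fibroblast-like and 0.35 in macrophage-like cells. With cells thinned to 1000 UMIs it was 0.32 in endothelial-like cells. For exercise over diabetic sedentary plain CPM moved it to -0.02, 0.39, 0.13, 0.14 and 0.07 in that order, and CPM without acinar, mitochondrial and haemoglobin genes moved it to 0.26 in acinar-like cells. With 122 endothelial-like cells in none, genes with 1 to 3 UMIs there, such as H2-Aa, Vwf and Mgp, have wide intervals.

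In what follows DN stands for diabetic sedentary over none and ED for exercise over diabetic sedentary; values are median log2 of lists in endothelial-like cells unless another class or a gene is named, and the cause was not tested. With acinar RNA subtracted, MHC class I DN was 0.36, acinar enzymes ED -1.25, beta cell dedifferentiation ED -0.50, nuclear oxidative phosphorylation 0.020 (DN) and -0.017 (ED), unfolded protein response DN 0.10, and acinar injury ED -0.035 in ductal-like and 0.34 in macrophage-like cells. With all acinar-RNA-rich barcodes, Prss3 in acinar-like cells was -0.25 (ED) and the endothelial identity list there 0.33. With at least 100 UMIs per member, ductal-like basement membrane DN was 0.032, fibroblast-like mesenchymal transition DN -0.36 and immediate early genes DN -0.25. With cells thinned to 1000 UMIs, VEGF signalling ED was -0.28 (fibroblast-like -0.29), fibroblast-like acinar enzymes ED 0.15, acinar-like capillary lipid DN -0.030, ductal-like basement membrane ED -0.041 and fibroblast-like mesenchymal transition DN -0.32. There too macrophage residence DN was 0.41, immediate early genes DN -0.026, oxidative phosphorylation DN 0.040 and unfolded protein response DN 0.0074.

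With doublets kept, endothelial-like shares were 1.71% (none) and 5.69% (diabetic sedentary) and the ED ratio 0.438. H2-Aa DN was then -0.89, MHC class II DN -0.86, MHC class I DN 0.33, acinar enzymes ED -0.17, beta cell dedifferentiation ED -0.44, oxidative phosphorylation ED -0.0037 and fibroblast-like mesenchymal transition DN -0.046. With libraries clustered apart, Igfbp5 DN was 1.33, acinar-like Prss3 ED -0.44, acinar-like endothelial identity ED 0.24, and macrophage residence DN -0.21 in ductal-like and 0.31 in endothelial-like cells. At a mitochondrial ceiling of 10%, acinar enzymes ED were -0.012, beta cell dedifferentiation ED -0.47 and oxidative phosphorylation ED -0.016. Without a cell filter, capillary lipid ED was -0.44, oxidative phosphorylation ED -0.024 and unfolded protein response DN -0.15. At resolution 0.5, acinar-like values ED were -0.31 for Prss3, 0.35 for endothelial identity and -0.18 for immediate early genes; at resolution 2 they were -0.15 for acinar injury and -0.29 for immediate early genes.

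Shares outside acinar-like and unnamed acinar-RNA-rich clusters were 7.95%, 22.4% and 15.6% with ratios of 2.82 (DN) and 0.695 (ED), and among cells not acinar 3.92% (none) and 10.0% (diabetic sedentary) with ratios of 2.55 and 0.262. Without acinar-RNA-rich endothelial sub-clusters, oxidative phosphorylation ED was -0.038. Without cells holding lymphatic or venule genes (5, 22 and 16 cells), beta cell dedifferentiation ED was -0.48, cell cycle ED -0.47, macrophage residence DN -0.17, oxidative phosphorylation DN -0.091 and unfolded protein response DN -0.13. Without the top cell, Madcam1 DN was 0.65.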

Other observations

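The values here were chosen after they were seen and are sums over all kept cells, without TMM scaling. Trypsinogen genes, which encode the precursors of trypsin and lie at 40948375 to 41525079 on chromosome 6, differed from one another between none and the diabetic libraries. Prss1 (ENSMUSG00000062751, 41458932 to 41463786) stood at 1.90, 309 and 358 CPM, a ratio of 163 (133 to 201) for diabetic sedentary over none. Gm5771, Gm10334 and 1810009J06Rik were 26.6, 15.5 and 17.2 times higher, and Try5 stood at 15610, 57870 and 35050 CPM. The abundant members 2210010C04Rik, Try4 and Prss2 were lower in diabetic sedentary (0.674, 0.843 and 0.885), and Try10 was nearly level (1.02). Acinar-like cluster 16, with 0, 197 and 68 cells, had Prss1, 1810009J06Rik, Gm5771 and Gm10334 among its leading genes. Prss1 was seen in 84, 3075 and 4122 cells, so it was not limited to this cluster. How much of these differences came from cluster 16 was not measured. The sum of 12 trypsinogen genes was 195600, 205200 and 167200 CPM, so that the difference lay in the share of single members more than in the total. These genes are near-identical copies, and the assignment of reads to single members is uncertain. The genotype of the mice of none is not given, so genetic background cannot be told apart from diabetes here.

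Islet hormone genes came mostly from cluster 20, with 6, 66 and 15 cells, except for Gcg (glucagon) in none, where 0 of 64 UMIs did. Ins2, which encodes insulin, stood at 649, 1766 and 1345 CPM, and Iapp, amylin, which beta cells release with insulin, at 51.9, 705 and 462 CPM, 13.6 times higher in diabetic sedentary than in none. Ins1, the other insulin gene, stood at 232, 189 and 142 CPM, and Pyy at 6.06, 57.5 and 120. In none, 1 cell each gave 6078 of 11743 UMIs of Ins1, 16432 of 32861 of Ins2, 1052 of 2627 of Iapp and 297 of 307 of Pyy. In exercise, 1 cell each gave 2832 of 5691 of Ins1, 26615 of 53940 of Ins2, 10901 of 18527 of Iapp and 1944 of 4800 of Pyy, so that all these levels rested on few cells. In diabetic sedentary, 8084 of 9683 UMIs of Gcg and 2386 of 2785 UMIs of Ppy (pancreatic polypeptide) came from 1 cell, so that no ratio is given for them.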
